A study of Mus musculus with 6 samples.

How the data were processed

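Liver RNA of 6 samples, 3 labelled vehicle and 3 labelled atractylodin, was extracted with Trizol, and 500 ng of total RNA went into each Lexogen QuantSeq 3' library, per the labels' protocols. The deposited files hold raw counts per gene symbol for each library, with no normalization. Per the submitters' processing notes, Bowtie2, bedtools and the mouse build mm10 were used, without versions or roles. Neither the gene annotation, the treatment of reads that match several genes, nor the strand setting is given in the sources used here. Reads of near-identical paralogs may therefore have been split or dropped, and reads of genes that overlap on opposite strands may not have been told apart. Whether reads were collapsed by molecular identifiers is likewise not given, so floors and other counting limits cover counting error only.

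Each file held 23282 rows in the same order, of which 44 repeated the symbol of an earlier row and were kept as rows of their own. No count was seen in any library for 4459 rows. No mitochondrially encoded gene was in the files, so that marker list had no members. Groups and replicate numbers came from the sample titles. Libraries were compared by a chi-square statistic of their counts per degree of freedom over rows with at least 10 counts summed over a pair, which was at least 2.75 for every pair, so no library was treated as a copy of another.

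Rows were filtered with filterByExpr and scaled by TMM in edgeR 4.0.16 under R 4.3.3, and 12505 were tested with the robust quasi-likelihood F-test (no covariates), with Benjamini-Hochberg adjustment at 0.05. Standard errors were the log2 fold change divided by the square root of F. CPM values used the TMM-scaled library sizes. Errors of log2 fold changes are SE, and other errors are the SD of 3 libraries unless called SE. The biological coefficient of variation was 15.0%. The floor of 3 counts, taken from total counts before TMM scaling, was 0.239 to 1.64 CPM per library.

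Lists of genes were fixed before the data were examined, from textbook knowledge: 23 functional lists and 17 marker lists of other cell types, liver zones and tissue handling. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted within each kind. Camera with an estimated correlation and fry were alternatives. With an estimated correlation none of the list calls held, and 2 functional lists and 1 marker list had an unadjusted p under 0.05. Counts of members that rose or fell used the adjustment over all tested genes and, separately, one over the list alone. Member counts of the hepatic stellate cell list are not reported here.

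The rule for named genes, also fixed before the data were examined, took the 8 largest rises and the 8 largest falls among genes past the threshold with an average log2 CPM of at least 2 and no overlap between groups. It added up to 3 passing members of each functional list in order of p (the 2 with the smallest p in a called list without any), the 2 members with the smallest p in 5 lists closest to the title of the study, and the most abundant and the smallest-p member of each called marker list. It gave 78 genes, of which 74 passed. Other genes were named after their values were seen, and the text says so. Gene positions are from GENCODE M21 on GRCm38, the build also called mm10, where 11993 of the 12505 tested rows matched 1 gene by symbol. Of the 78 genes, 18 overlapped another annotated gene on the same strand and 29 on the opposite strand, among them Pklr, Cxcl10, Ccnd1, Nr1d1, Mogat1 and C8g.

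The test was tried on simulated data with the means and library sizes of these libraries over 12505 genes. Of 100 genes changed 2-fold, 65 were recovered with the right sign, and of 100 changed 1.5-fold, 33. Of 109 calls 11 were false. A raised list was called and none of 20 unchanged lists was. Simulated genes were drawn independently of each other, so this could not show false calls of lists whose members are correlated.

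Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, RLE and upper quartile scaling, total counts alone or without the 20 most abundant genes, no filter, a mean CPM of at least 5, the replicate number as a block, and leaving out each library. Chosen after seeing the data were all libraries thinned to the depth of vehicle 1, library sizes without Rn45s, and list counts without vehicle 1. No other split by batch was made, since the labels give no batch or date. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.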

Results

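The series asked how atractylodin, a compound of Atractylodes plants, acts on the fatty liver of mice kept on a high-fat diet. Male C57BL/6N mice were put on the diet at 8 weeks of age and stayed on it for 12 weeks. After 8 weeks of diet they received vehicle or atractylodin at 10 mg/kg by mouth, 5 days per week for 4 weeks, and liver RNA was then profiled by QuantSeq, a method that sequences the 3' end of each transcript. There were 3 vehicle and 3 atractylodin libraries. The labels number the libraries within each group without saying that each came from a separate animal, so p-values measure the spread between these libraries. No mice on a control diet were included, so every value compares atractylodin with vehicle on the high-fat diet.

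The total count was 1831461 for vehicle 1, 11120089 for vehicle 2 and 12111553 for vehicle 3. It was 10152640, 9871762 and 12565393 for atractylodin 1, 2 and 3. Vehicle 1 was therefore the shallowest library and held counts in 13887 of the 23282 rows, against 16076 to 16209 in the other 5 libraries. By total counts before TMM scaling, a count of 3 equalled 1.64 CPM (counts scaled to a common library size) in vehicle 1 and 0.304 CPM or less in the others. Genes of a few CPM were therefore measured less precisely in the vehicle group. CPM values of genes use TMM-scaled sizes, on which these floors differ slightly. Albumin took 4.55% to 5.67% of counts, the ribosomal RNA row Rn45s 4.14% to 5.41%, and the 10 most abundant genes 19.9% to 20.97%. Spearman correlations of counts were 0.955 to 0.968 within the vehicle group, 0.963 to 0.965 within the atractylodin group and 0.949 to 0.964 between groups. The first principal component held 56.0% of the variance of the 500 most variable genes and set vehicle 1, at -39.5, apart from the other 2 vehicle libraries at -1.27 and -0.47. The atractylodin libraries lay at 12.62 to 15.2 on that component.

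**Figure D1:**
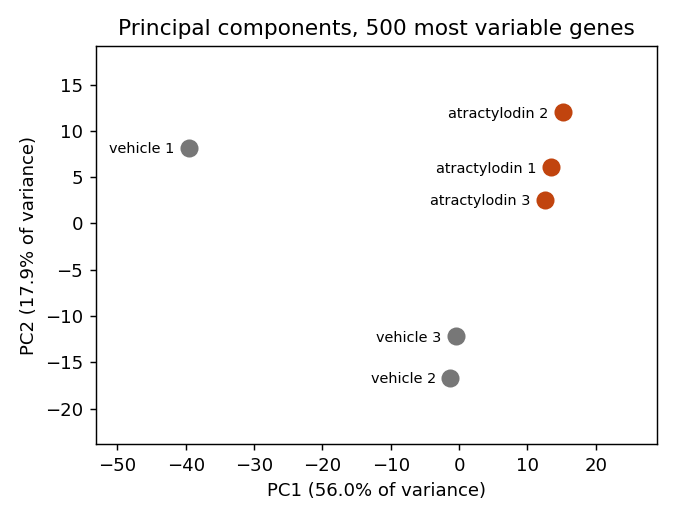
First against second principal component of log2 CPM for the 500 most variable genes, with the share of variance on each axis and 1 point per library (vehicle grey, atractylodin red-brown). Vehicle 1, the shallowest library, lies at -39.5 on the first component, and the 3 atractylodin libraries lie between 12.62 and 15.2.

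Livers of atractylodin-treated mice had higher expression of Zbtb16, Lpin1, Pck1 and several cytochrome P450 genes, though other P450 genes such as Cyp3a11 were lower. Expression was also lower for the fatty acid synthesis gene Fasn, the interferon-stimulated gene Isg15, Ccnd1 and Tsc22d1. Of 12505 rows tested with edgeR's quasi-likelihood test, 906 passed an adjusted p of 0.05, 490 higher and 416 lower with atractylodin. Among them 99 were at least 2-fold higher and 105 at least 2-fold lower. The 2 groups did not overlap for 896 of the 906 genes, and for 3272 of all tested genes, which is 26.2% where chance gives 10%. The count fell to 494 without vehicle 1 and to 467 without vehicle 3. Scaling by total counts alone called 312 genes higher and 707 lower, so the balance of rises and falls depended on the scaling.

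The largest rise by the rule for named genes was that of Zbtb16, which encodes a zinc-finger transcription factor (GRCm38 chromosome 9, 48654297 to 48836222). It went from 4.16 ± 1.74 CPM (SD, n = 3) with vehicle to 32.9 ± 1.86 CPM with atractylodin, a log2 fold change of 2.78 ± 0.19 (SE, edgeR adjusted p = 1.15e-07). Lpin1, a phosphatidate phosphatase of triglyceride synthesis that also acts as a transcriptional coactivator (chromosome 12, 16535669 to 16610966), rose from 74.5 ± 25.2 to 279 ± 17.4 CPM (SD, n = 3), with a log2 fold change of 1.86 ± 0.22 and an adjusted p of 0.00644. The aldo-keto reductase gene Akr1c19 (chromosome 13, 4228700 to 4252843) rose 3.19-fold (log2 1.67 ± 0.12, adjusted p = 1.40e-06) and the basic helix-loop-helix gene Atoh8 3.25-fold (adjusted p = 0.00283). The other 4 of the 8 largest rises were cytochrome P450 rows: Cyp2c29 (569 ± 152 to 2263 ± 685 CPM), Cyp2a5 (365 ± 100 to 1328 ± 278 CPM), Cyp2a4 (49.9 ± 17.6 to 188 ± 37.3 CPM) and the pseudogene Cyp2c53-ps. Cyp2c53-ps overlaps Cyp2c29 on the same strand, and Cyp2a4 and Cyp2a5 are near-identical paralogs, so the share of each within its pair is uncertain. The call of Cyp2c29 was lost in 5 of the 6 fits that left out 1 library, that of Cyp2a4 in 3 and that of Cyp2a5 in 1.

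Among the falls, Tsc22d1, a leucine-zipper gene first described as stimulated by TGF-beta (chromosome 14, 76414961 to 76507765), went from 155 ± 17.2 to 35.2 ± 4.31 CPM (SD, n = 3), a log2 fold change of -2.14 ± 0.12 (SE, adjusted p = 2.70e-09). The water channel gene Aqp8 (chromosome 7, 123462291 to 123468004) fell from 65.3 ± 5.66 to 14.6 ± 4.38 CPM (log2 -2.16 ± 0.17, adjusted p = 1.33e-05). Ccnd1, encoding cyclin D1 (chromosome 7, 144929931 to 144939925), fell from 71.1 ± 16.7 to 18.3 ± 1.65 CPM (log2 -1.95 ± 0.17, adjusted p = 2.45e-05). The other 5 largest falls were of genes at lower levels. They were the pseudogene 9030619P08Rik (23.3 ± 6.18 to 4.71 ± 2.28 CPM), the T-cell gene Themis (6.47 ± 1.75 to 1.37 ± 1.04 CPM), Rgs12 (7.54 ± 1.47 to 1.92 ± 0.93 CPM), the interferon-induced GTPase gene Gbp6 (6.47 ± 1.86 to 1.89 ± 0.93 CPM) and Mogat1 (7.84 ± 2.75 to 2.26 ± 0.46 CPM), with adjusted p from 0.00283 to 0.00782. The call of Gbp6 was lost in 1 of the 6 fits that left out 1 library.

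Genes of de novo lipogenesis were lower with atractylodin. Of 22 tested members, 7 fell, 1 rose and 14 did not pass, while adjusted over the list alone 11 fell and 1 rose. The median log2 fold change was -0.39 and camera gave an adjusted p of 0.000222 for the list, against an adjusted p of 0.206 with an estimated correlation. Pklr, the liver pyruvate kinase that feeds carbon into fatty acid synthesis (chromosome 3, 89136142 to 89146784), fell from 21.8 ± 4.87 to 9.05 ± 1.75 CPM (SD, n = 3), with a log2 fold change of -1.32 ± 0.19 and an adjusted p of 0.000517. Mid1ip1, an activator of acetyl-CoA carboxylase, fell from 61.2 ± 1.58 to 35.6 ± 6.97 CPM (adjusted p = 0.00144). The rise was that of Me1, which encodes the NADPH-producing malic enzyme (1.61-fold, adjusted p = 0.000712). Among members named after their values were seen, Srebf1, the transcription factor that drives the pathway, fell 2.29-fold (adjusted p = 0.00391) and Fasn, encoding fatty acid synthase, fell 1.83-fold (adjusted p = 0.00565). Scd1, the stearoyl-CoA desaturase, stood at 1042 ± 676 CPM with vehicle and 163 ± 23.3 CPM with atractylodin and did not pass (adjusted p = 0.0763). Without vehicle 1, 7 falls and 1 rise were called.

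Fatty acid oxidation and ketogenesis genes moved the other way by a small amount. Of 36 tested members 6 rose and none fell, 9 rose adjusted over the list alone, and the median log2 fold change was 0.17 (camera adjusted p = 0.0016, and adjusted p = 0.706 with an estimated correlation). The fatty acid omega-hydroxylase genes of the Cyp4a cluster on chromosome 4 led the list in order of p, though not in size of change. Cyp4a14 rose from 5289 ± 608 to 9349 ± 1903 CPM (SD, n = 3), Cyp4a10 from 1753 ± 272 to 2724 ± 343 CPM and Cyp4a31 from 22.3 ± 1.91 to 40.7 ± 6.94 CPM, with adjusted p of 0.00454, 0.00422 and 0.00177. These 3 are close paralogs whose reads may have been shared in counting. Members named after their values were seen include Fgf21, a fasting-responsive hormone (2.15-fold, adjusted p = 0.00649), and Pdk4, the kinase that restrains pyruvate oxidation (0.98 ± 0.91 to 4.47 ± 0.83 CPM, adjusted p = 0.0177). The call of Cyp4a14 was lost without vehicle 2, and that of Pdk4 in 2 of the 6 fits that left out 1 library. Without vehicle 1, 6 members rose, and under scaling by total counts 6 rose and 1 fell.

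Cholesterol synthesis genes were lower as a list (median log2 fold change -0.41, camera adjusted p = 0.00434), with an adjusted p of 0.723 with an estimated correlation. A single member of 25 passed in edgeR over all genes, Dhcr7, the last enzyme of the pathway to cholesterol (12.3 ± 1.68 to 5.35 ± 1.48 CPM, adjusted p = 0.0071), and 5 fell adjusted over the list alone. Scaling by total counts gave 5 falls over all genes, and DESeq2 gave 2 calls. The call of the list was lost without vehicle 3 (adjusted p = 0.353) and without atractylodin 3 (adjusted p = 0.0511). Lipid uptake and droplet genes were not called as a list (camera adjusted p = 0.181, median -0.16). Within it, 3 of 30 members fell and 1 rose, and adjusted over the list alone 5 fell and 2 rose. The falls were those of Mogat1, a monoacylglycerol acyltransferase, the fatty acid translocase Cd36 (88.1 ± 9.80 to 53.3 ± 12.0 CPM, adjusted p = 0.018) and the droplet coat gene Plin3 (68.5 ± 11.4 to 48.1 ± 0.62 CPM, adjusted p = 0.0177). The rise, seen after the fact, was of Pnpla2, encoding adipose triglyceride lipase. Without vehicle 1 only 1 fall and no rise were called, and under scaling by total counts 4 falls and 0 rises. The calls of Cd36 and Plin3 were each lost in 2 of the 6 fits that left out 1 library, and that of Pnpla2 in 4.

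Lipoprotein assembly and export genes went both ways and were not called as a list (camera adjusted p = 0.742, median 0.02, which turned to -0.06 under scaling by total counts). Of 19 members 3 rose and 3 fell, both over all genes and adjusted over the list alone. Apoa5, an apolipoprotein that promotes triglyceride clearance, rose from 943 ± 87.0 to 1665 ± 202 CPM (SD, n = 3, adjusted p = 0.00019). Angptl4, an inhibitor of lipoprotein lipase, rose from 81.2 ± 12.58 to 139.8 ± 18.4 CPM (adjusted p = 0.00154). The HDL receptor gene Scarb1 fell 1.37-fold (adjusted p = 0.00758), a call lost without vehicle 2. The remaining calls, named after their values were seen, were a rise of Sar1b and falls of Apoc2 and Abca1, of which the first was lost in 6 and the others in 4 of the 6 fits that left out 1 library. Without vehicle 1, 2 rises and 1 fall were called.

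**Figure D2:**
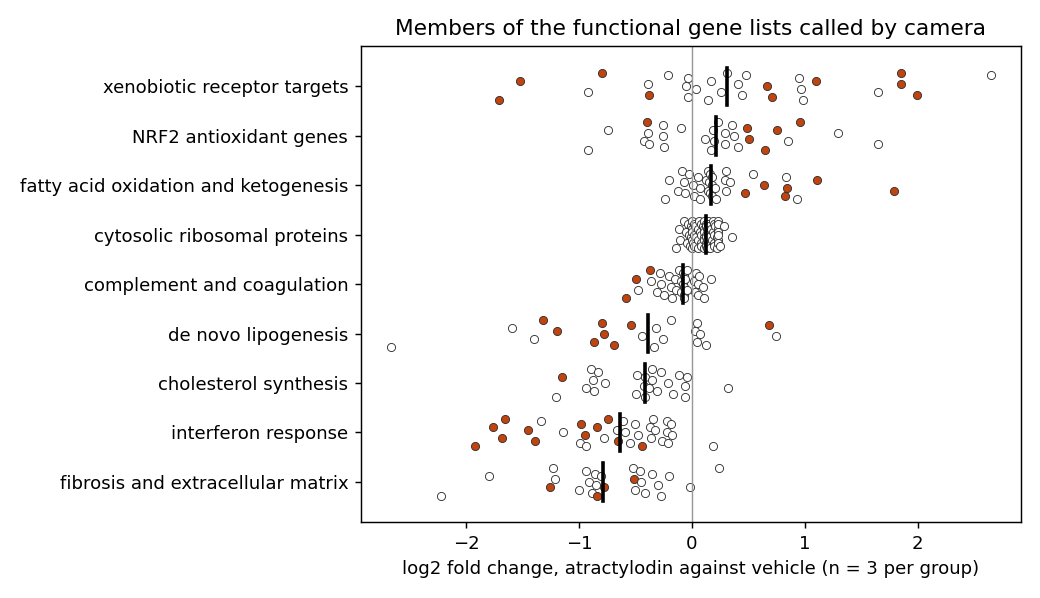
Log2 fold change of atractylodin against vehicle for each tested member of the 9 functional lists called by camera, with filled points passing an adjusted p of 0.05 over all genes and black bars at list medians. Interferon response and fibrosis members lie mostly below 0, with medians of -0.63 and -0.79, and ribosomal protein genes cluster near their median of 0.12.

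Interferon-stimulated genes were lower as a list, with 22 of its members not passing. Of 34 tested members 33 had lower estimates with atractylodin, 12 fell over all genes and 18 adjusted over the list alone, and none rose. The median log2 fold change was -0.63 and the camera adjusted p was 4.69e-12, with an adjusted p of 0.206 with an estimated correlation. Isg15, a ubiquitin-like interferon effector (chromosome 4, 156199424 to 156200818), fell from 19.3 ± 2.22 to 5.59 ± 0.25 CPM (SD, n = 3), with a log2 fold change of -1.76 ± 0.19 and an adjusted p of 3.31e-05. Ifit3 fell from 25.4 ± 1.81 to 7.84 ± 2.42 CPM (adjusted p = 0.000104) and Oasl1 from 12.1 ± 0.29 to 3.81 ± 0.77 CPM (adjusted p = 0.000403). Ifit3 has a near-identical neighbour, Ifit3b, with which its reads may have been shared. Without vehicle 1, 6 members fell. Macrophage markers also had lower estimates beside this list. Their median log2 fold change was -0.31 and their camera adjusted p was 0.0195, with an adjusted p of 0.843 with an estimated correlation. The only one of 22 macrophage markers to pass in edgeR, where DESeq2 called 2 and limma-voom 0, was the tetraspanin gene Cd63 (17.3 ± 7.35 to 8.09 ± 1.15 CPM, adjusted p = 0.0364), a call lost in 5 of the 6 fits that left out 1 library, and the most abundant, Cd5l, stood at 124 ± 29.3 and 102.1 ± 25.6 CPM (adjusted p = 0.577). The macrophage call was lost without vehicle 2 (adjusted p = 0.589), without atractylodin 2 (adjusted p = 0.153) and without atractylodin 3 (adjusted p = 0.0559).

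Inflammatory mediators were not called as a list (camera adjusted p = 0.355, median -0.21). Of 19 tested members 2 chemokine genes fell, both near the detection limit of vehicle 1, and the same 2 adjusted over the list alone. Cxcl10, which interferon induces, went from 4.54 ± 1.20 to 1.05 ± 0.85 CPM (SD, n = 3, adjusted p = 0.0153) and Ccl2, a monocyte attractant, from 1.93 ± 0.42 to 0.36 ± 0.22 CPM (adjusted p = 0.0203). Neither passed without vehicle 1, and over the 6 fits that left out 1 library the calls were lost in 3 and 5. None of 26 acute phase genes passed in edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.232, median -0.10), while 2 had an unadjusted p under 0.05 and 2 passed in DESeq2 and in limma-voom. Complement and coagulation genes were lower as a list by a median log2 fold change of -0.08 (camera adjusted p = 0.0281, and adjusted p = 0.706 with an estimated correlation). Its 3 falls of 35 members, with 5 adjusted over the list alone, were of Serpinf2, the plasmin inhibitor (1.40-fold lower, adjusted p = 0.023), the complement gene C8g (1.29-fold lower, adjusted p = 0.0291) and the coagulation factor gene F11 (1.49-fold lower, adjusted p = 0.0336). None of these 3 passed without vehicle 1, scaling by total counts gave 6 falls, and the call of the list was lost without vehicle 1 (adjusted p = 0.177), vehicle 3 (adjusted p = 0.0963) or atractylodin 2 (adjusted p = 0.129).

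Genes of fibrosis and extracellular matrix were lower with atractylodin. Of 26 tested members 25 had lower estimates, 4 fell over all genes and 15 adjusted over the list alone, and none rose. The median log2 fold change was -0.79 (camera adjusted p = 2.33e-06, and adjusted p = 0.706 with an estimated correlation). Sparc, a collagen-binding matrix protein gene (chromosome 11, 55394500 to 55423183), fell from 80.8 ± 13.4 to 45.6 ± 5.24 CPM (SD, n = 3), with a log2 fold change of -0.84 ± 0.13 and an adjusted p of 0.000706. Col5a1 fell from 9.32 ± 2.45 to 3.90 ± 0.06 CPM (adjusted p = 0.00697) and Col4a2 from 19.0 ± 4.08 to 11.2 ± 2.00 CPM (adjusted p = 0.0204). The last call, seen after the fact, was of Tgfbi. The fibrillar collagen genes Col1a1 (13.2 ± 9.88 to 4.07 ± 1.20 CPM, adjusted p = 0.144) and Col3a1 (28.1 ± 17.99 to 6.36 ± 2.83 CPM, adjusted p = 0.127), also named after the fact, varied widely between vehicle libraries and did not pass. Without vehicle 1, 3 members fell, and over the 6 fits that left out 1 library the calls of Col5a1, Col4a2 and Tgfbi were lost in 1, 3 and 5.

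Markers of 3 other liver cell types were measured beside this list. Hepatic stellate cell markers were not called (18 tested, camera adjusted p = 0.767, median -0.08). Cholangiocyte markers were lower (median -0.92, camera adjusted p = 0.000687, and adjusted p = 0.249 with an estimated correlation). Of 7 tested members, 3 fell over all genes and 5 adjusted over the list alone. Sox9 went from 28.3 ± 7.12 to 14.3 ± 1.97 CPM (SD, n = 3, adjusted p = 0.00434), Tstd1 from 24.4 ± 4.84 to 10.8 ± 2.23 CPM (adjusted p = 0.00156), and Spp1, which encodes osteopontin, fell 2.23-fold (adjusted p = 0.00288). The same number fell without vehicle 1. Liver endothelial markers were not called by camera (adjusted p = 0.121, median -0.19) but were called lower by fry (adjusted p = 0.00303), with falls of Stab2, Fcgr2b and Ptprb and rises of Lyve1 and Bmp2 among 19 members, while adjusted over the list alone 6 fell and 2 rose and without vehicle 1 none passed. Scaling by total counts gave 5 falls and 0 rises. The calls of Stab2, Fcgr2b, Lyve1 and Bmp2 were each lost in 5 of the 6 fits that left out 1 library, and that of Ptprb in 6. Spp1 and the endothelial genes were named after their values were seen.

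Genes of xenobiotic metabolism were higher as a list, with members going both ways. Of 29 tested targets of xenobiotic receptors 6 rose and 4 fell, and adjusted over the list alone 12 rose and 4 fell. The median log2 fold change was 0.31 (camera adjusted p = 0.00382, and adjusted p = 0.706 with an estimated correlation). Por, the electron donor of microsomal cytochromes P450 (chromosome 5, 135670033 to 135735326), rose from 406 ± 45.5 to 869 ± 117 CPM (SD, n = 3), with a log2 fold change of 1.10 ± 0.11 and an adjusted p of 2.59e-05. Cyp3a11, a classical target of the pregnane X receptor, fell from 377 ± 102 to 131.5 ± 4.55 CPM (adjusted p = 0.0032), and Cyp2b9 fell from 92.4 ± 4.58 to 53.0 ± 7.31 CPM (adjusted p = 0.000319). The other 2 falls were of Cyp2b13 and, named after its value was seen, Aldh1a7, lost in 3 and 4 of the 6 fits that left out 1 library. Cyp2b10, a classical target of the constitutive androstane receptor that was also looked up after the fact, stood at 5.50 ± 1.68 and 31.5 ± 19.4 CPM (adjusted p = 0.0871). Without vehicle 1, 5 members rose and 2 fell. The Cyp2b, Cyp2c and Cyp3a genes are paralogous families, so reads of single members are uncertain.

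**Figure D3:**
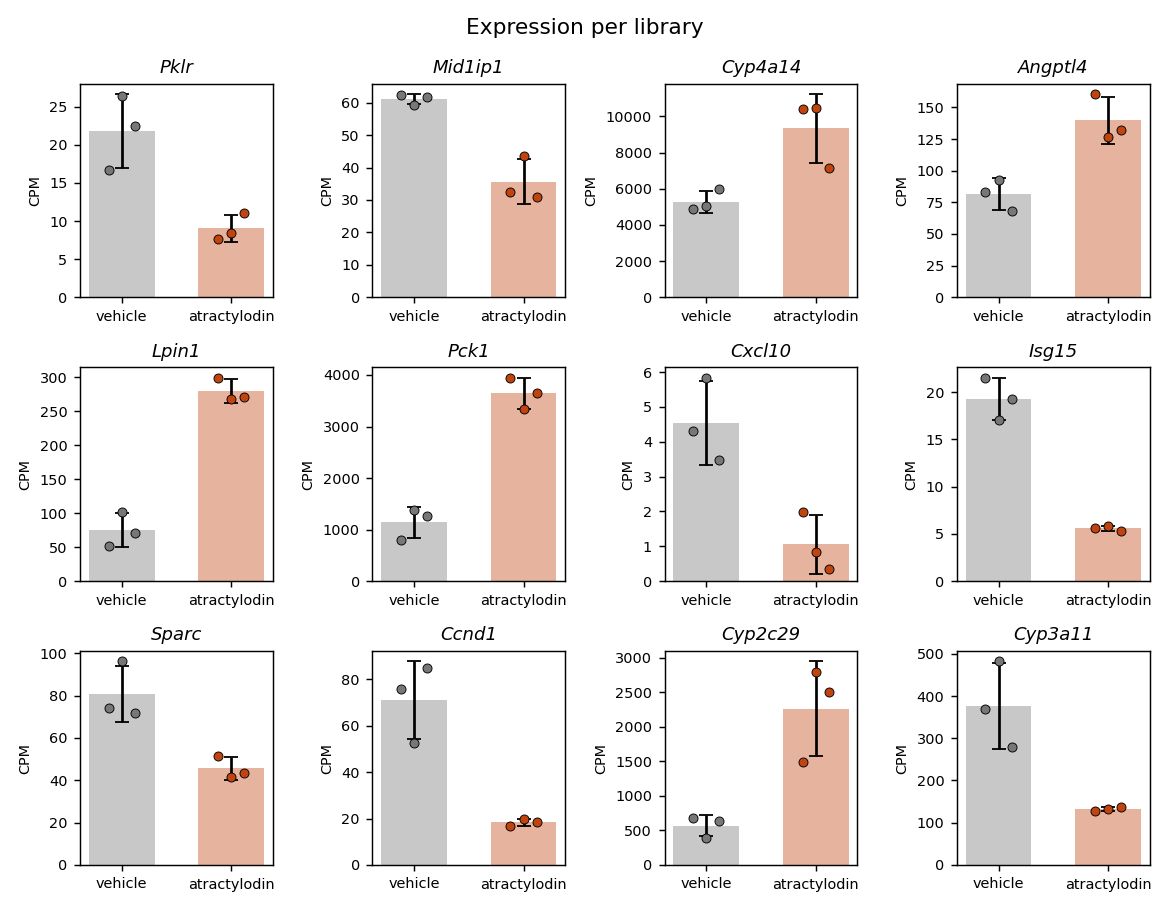
CPM of 12 named genes per library, with bars at group means, whiskers of 1 SD (n = 3) and 1 point per library. Lpin1 and Pck1 were higher in each atractylodin library than in any vehicle library, and Isg15, Ccnd1 and Cyp3a11 were lower.

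NRF2 antioxidant genes were higher as a list (median 0.22, camera adjusted p = 0.019, and adjusted p = 0.706 with an estimated correlation). Of 28 members, 5 rose and 1 fell, and adjusted over the list alone 9 rose and 3 fell. Ephx1, microsomal epoxide hydrolase, rose from 262 ± 38.2 to 512 ± 10.0 CPM (SD, n = 3, adjusted p = 3.31e-05). Gclc, the catalytic subunit of glutathione synthesis, rose from 258 ± 31.8 to 437 ± 25.2 CPM (adjusted p = 0.000226), and Txnrd1 from 74.9 ± 3.49 to 118 ± 10.4 CPM (adjusted p = 0.000644). The remaining calls, named after their values were seen, were rises of Gclm and Srxn1 and a fall of Taldo1, lost in 5, 2 and 3 of the 6 fits that left out 1 library. The call of the list was lost without vehicle 1 (adjusted p = 0.0942, with 3 members higher and 1 lower, against 4 and 3 under scaling by total counts), vehicle 3 (adjusted p = 0.0789) or atractylodin 3 (adjusted p = 0.0951).

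Sex-biased liver genes did not pass as lists. The male-biased list had a median log2 fold change of 0.19 (camera adjusted p = 0.0677), with 7 rises and 3 falls among 23 members and, adjusted over the list alone, 8 rises and 3 falls. Mup1 and Mup7, major urinary protein genes of near-identical sequence, rose from 2052 ± 300.4 to 3447 ± 356 CPM and from 1685 ± 344 to 3642 ± 554 CPM (SD, n = 3, adjusted p = 0.000712 and 0.00186), and Ugt2b1 rose 1.42-fold (adjusted p = 0.00242). Its falls, named after their values were seen, were of Elovl3, Hsd3b2 and Nudt7. The female-biased list had a median of -0.10 (camera adjusted p = 0.682), with rises of Cyp2a4, Fmo2 and, seen after the fact, Cyp39a1, and falls of Cyp2b9 and Cyp2b13 among 12 members. Adjusted over the list alone, 3 rose and 4 fell. With 1 library left out, the calls of Nudt7, Cyp39a1, Cyp2a4, Cyp2b13 and Fmo2 were lost in 4, 3, 3, 3 and 1 of 6 fits. Without vehicle 1 the male-biased list held 5 rises and 2 falls and the female-biased list 2 and 1. Bile acid genes were not called as a list (camera adjusted p = 0.692, median 0.04, which turned to -0.04 under scaling by total counts). Of 25 members, Cyp7b1 of the alternative synthesis pathway rose 1.67-fold (adjusted p = 0.0148), while the bile salt export pump gene Abcb11 (adjusted p = 0.0198), Akr1d1 (adjusted p = 0.0389) and, named after its value was seen, Hsd3b7 fell. Adjusted over the list alone 4 rose and 3 fell, 1 rise and 1 fall were called without vehicle 1, and over the 6 fits that left out 1 library the calls of these 4 genes were lost in 4 or 5.

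Glucose-handling genes went both ways (camera adjusted p = 0.188, median 0.21). Pck1, the rate-limiting enzyme of gluconeogenesis (chromosome 2, 173153048 to 173159273), rose from 1145 ± 301.2 to 3644 ± 305 CPM (SD, n = 3), with a log2 fold change of 1.67 ± 0.19 and an adjusted p of 0.00247. The transcription factor gene Foxo1, which insulin signalling restrains, rose 1.59-fold (adjusted p = 0.00676) and the glycogen synthase gene Gys2 1.47-fold (adjusted p = 0.00758). In all, 3 of 24 members rose and 4 fell, and adjusted over the list alone 4 rose and 4 fell. The falls, named after their values were seen, were of Pcx, Slc2a2, Pygl and Gckr. Leaving out 1 library ended the call of Pcx in 3 of 6 fits and those of Slc2a2, Pygl and Gys2 in 1, the fit without vehicle 3. Igfbp1, a gene that insulin represses, was looked up after the fact and stood at 49.1 ± 19.6 and 403.2 ± 204 CPM (adjusted p = 0.0796). Without vehicle 1, 3 rose and 3 fell.

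Of 20 circadian clock genes 6 rose and 3 fell, with 8 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.17, median 0.22). Per1 rose from 10.8 ± 1.24 to 28.4 ± 7.75 CPM (SD, n = 3, adjusted p = 0.000712) and Rora 1.37-fold (adjusted p = 0.00454). Nr1d1, the repressor REV-ERB alpha, fell from 25.8 ± 2.79 to 12.0 ± 2.28 CPM (adjusted p = 0.000994), as did, named after their values were seen, the clock output genes Dbp and Hlf, the latter lost in 4 of the 6 fits that left out 1 library. Without vehicle 1, 5 rose and 2 fell, and under scaling by total counts 4 rose and 4 fell. The stress response of the endoplasmic reticulum was not called (camera adjusted p = 0.188, median -0.16). Of 29 members the degradation gene Herpud1 rose from 426 ± 31.3 to 897 ± 192 CPM (adjusted p = 0.000945), while the chaperone genes Calr (1.73-fold lower, adjusted p = 0.0162) and Hsp90b1 (1.42-fold lower, adjusted p = 0.0137) fell. A rise of Asns and a fall of Pdia6, named after their values were seen, made 2 rises and 3 falls, or 4 and 9 adjusted over the list alone, 1 and 2 without vehicle 1, and 2 and 8 under scaling by total counts. The call of Asns was lost in 6 of the 6 fits that left out 1 library, that of Pdia6 in 3, that of Calr in 2 and that of Hsp90b1 in 1.

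Amino acid catabolism was not called as a list (camera adjusted p = 0.619), with a median of 0.05, a mean of -0.04 and a downward test, and the median turned to -0.04 under scaling by total counts. Of 36 members, 5 fell and 2 rose, with 8 and 3 adjusted over the list alone, 5 and 1 without vehicle 1, and 8 and 1 under scaling by total counts. The betaine-homocysteine methyltransferase gene Bhmt fell from 2651 ± 119 to 1378 ± 194 CPM (SD, n = 3, adjusted p = 5.05e-05). The glycine decarboxylase gene Gldc fell 2.01-fold (adjusted p = 0.000288) and the histidine catabolism gene Uroc1 1.48-fold (adjusted p = 0.00232). The other calls, named after their values were seen, were falls of Hal and Cbs and rises of Mat1a and Ahcy, of which Mat1a was lost in 5 of the 6 fits that left out 1 library. Autophagy and lysosome genes were not called (camera adjusted p = 0.269, median 0.06, which turned to -0.03 under scaling by total counts). There, 4 of 34 rose both over all genes and adjusted over the list alone, namely the autophagy receptor gene Sqstm1 (1.53-fold, adjusted p = 0.00053), Bnip3 (1.57-fold, adjusted p = 0.000774), Map1lc3b (1.27-fold, adjusted p = 0.0283) and, seen after the fact, Gabarapl1, and 2 rose without vehicle 1. The calls of Map1lc3b and Gabarapl1 were each lost in 4 of the 6 fits that left out 1 library and under scaling by total counts, where 2 members of the list rose. Cytosolic ribosomal protein genes were higher as a list by a median of 0.12 (camera adjusted p = 0.00308, and adjusted p = 0.706 with an estimated correlation), yet none of the 77 passed in edgeR over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom. The members with the smallest p were Rplp2 (adjusted p = 0.125) and Rpl13a (adjusted p = 0.128), and the call of the list was lost without vehicle 2 (adjusted p = 0.0599) and under scaling by total counts (adjusted p = 0.0641). None of 72 nuclear genes of oxidative phosphorylation passed in edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.188, median -0.04), with 5 at an unadjusted p under 0.05, 0 in DESeq2 or limma-voom and 3 falls in edgeR under scaling by total counts. Of 22 cell cycle genes, Ccnd1 fell and no other passed, with the same count adjusted over the list alone and without vehicle 1 (camera adjusted p = 0.619, median -0.05).

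Heat shock genes were higher with atractylodin (median 0.48, camera adjusted p = 8.03e-05, and adjusted p = 0.465 with an estimated correlation). Of 15 members 5 rose, 7 adjusted over the list alone and 3 without vehicle 1, and none fell. Hsph1 rose from 49.1 ± 7.58 to 83.5 ± 14.7 CPM (SD, n = 3, adjusted p = 0.00308) and Hsp90ab1 1.27-fold (adjusted p = 0.0484), the latter lost in 4 of the 6 fits that left out 1 library. The other 3 rises, named after their values were seen, were of Hspd1, Bag3 and Chordc1, of which the first was lost in 1 and Bag3 in 4 of those fits. Immediate early genes, which respond to handling of tissue, were higher as a list (median 0.29, camera adjusted p = 0.0124, and adjusted p = 0.843 with an estimated correlation). Of 18 members, Dusp6 (1.58-fold, adjusted p = 0.0177) and, seen after the fact, Ier3 rose, 4 rose adjusted over the list alone, 1 without vehicle 1 and 1 under scaling by total counts. Their calls were lost in 2 (Dusp6) and 5 (Ier3) of the 6 fits that left out 1 library. The most abundant member, Jund, stood at 57.5 ± 6.08 and 70.5 ± 14.8 CPM (adjusted p = 0.299). The immediate early call was lost without vehicle 1 (adjusted p = 0.271) and without atractylodin 3 (adjusted p = 0.0843).

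Hepatocyte markers were not called (camera adjusted p = 0.767, median 0.03), with Hnf4a the 1 rise among 13 members. Pericentral markers had 3 rises (Cyp2a5, Cyp1a2, Slc1a2) and 5 falls (Lgr5, Rhbg, Lect2, Gulo, Rgn) among 15 members (camera adjusted p = 0.796, median -0.14). Periportal markers had a rise of Pck1 and falls of Hal, Gldc and Aldh1b1 among 15 (camera adjusted p = 0.767, median 0.03, mean -0.09). Without vehicle 1 the pericentral list held 1 rise and 4 falls (1 and 5 under scaling by total counts), and the hepatocyte and periportal lists held as many calls as with all libraries. Adjusted over the list alone, 5 pericentral markers rose and 5 fell, and the counts of the hepatocyte and periportal lists did not differ. Apart from those also in the named lists above, these genes were named after their values were seen. Of the 6 fits that left out 1 library, 5 ended the calls of Slc1a2 and Rgn, 4 those of Cyp1a2, Rhbg and Gulo, 2 that of Lgr5 and 1 those of Cyp2a5 and Aldh1b1. The medians of the hepatocyte and periportal lists turned negative under scaling by total counts. Antigen presentation genes (10 tested, median -0.41), T and NK cell markers (6 tested, median 0.26), the 1 tested B and plasma cell marker (-0.12), neutrophil markers (5 tested, median 0.84 with a downward test) and adipocyte markers (4 tested, median -0.37) held no gene that passed in edgeR over all genes or adjusted over the list alone, with camera adjusted p from 0.538 to 0.767. At an unadjusted p under 0.05 they held 2, 1, 0, 0 and 1 genes, and DESeq2 called 1 antigen presentation gene and limma-voom none. Among erythroid markers Alas2 fell (8 tested, median 0.07 with a downward test, -0.01 under scaling by total counts, camera adjusted p = 0.831), and among pancreatic acinar markers Cpb1 rose (2 tested, median 0.55, camera adjusted p = 0.875), both named after their values were seen. Adjusted over the list alone, 1 erythroid marker fell, and of the acinar markers 1 rose and 1 fell. The call of Cpb1 was lost in 3 of the 6 fits that left out 1 library.

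As a description without a threshold, the mean z score of each list was compared between groups with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Of 39 lists 10 reached that value, with no overlap between groups. Single genes did not overlap in 26.2% of cases, where chance gives 10%. The uncalled lists of glucose handling, circadian clock, nuclear oxidative phosphorylation and liver endothelial genes were among the 10. Reaching that value therefore does not set the called lists apart. The rest of the 10 were de novo lipogenesis, fatty acid oxidation and ketogenesis, interferon response, fibrosis, cholangiocyte and heat shock genes, while the other 7 called lists overlapped between groups. Their exact permutation p was 0.2 for xenobiotic targets, NRF2 genes, ribosomal proteins and immediate early genes, 0.3 for the macrophage and complement lists and 0.4 for cholesterol synthesis.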

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

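Thinning all libraries to the depth of vehicle 1, leaving out the Rn45s row and counting list members without vehicle 1 were chosen after seeing the data, and the other alternatives before. With DESeq2, limma-voom, the likelihood ratio test, RLE, upper quartile or either filter, the number of called genes went from 906 to between 806 and 1345. Of the 906 genes, 734 stayed called with DESeq2, 754 with limma-voom, 793 with the likelihood ratio test and up to 902 (no filter) with the others. Total counts alone gave 312 genes higher and 707 lower, total counts without the 20 most abundant genes 324 and 690, and library sizes without Rn45s 318 and 681. These settings shift all genes down alike (median log2 fold change -0.09 with total counts, -0.00 with TMM). Thinning gave 554 calls (283 higher, 271 lower) and kept 469 of the 906, with fewer genes tested. With the replicate number as a block 811 genes were called, 727 of them among the 906. Correlations of replicates with the same number gave no sign of pairing. Leaving out 1 library gave 467 to 751 calls, 236 to 400 higher and 215 to 362 lower, with fewer samples. These fits kept 423 (without vehicle 3) to 631 (without atractylodin 1) of the 906.

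Of the 9 functional lists none was called with an estimated correlation and 2 with fry, and of the 4 marker lists 0 with an estimated correlation. Fry called 3 marker lists, 2 of the 4 and the endothelial list (adjusted p = 0.00303). Leaving out 1 library gave 6 to 11 functional and 2 to 4 marker lists. The adjusted p with an estimated correlation was 0.206 for lipogenesis and interferon response, 0.723 for cholesterol synthesis, 0.249 for cholangiocyte, 0.465 for heat shock, 0.843 for macrophage and immediate early genes, and 0.706 for the remaining 6 called lists. With fry it was 0.403 for cholesterol synthesis, 0.166 for fatty acid oxidation, 0.143 for fibrosis, 0.141 for xenobiotic targets, 0.173 for NRF2 genes, 0.167 for ribosomal proteins and for complement, 0.533 for macrophage and 0.359 for immediate early genes. Total counts alone gave 0.0641 for ribosomal proteins and 0.0600 for macrophage, and thinning 0.0507 for complement and 0.0904 for macrophage. The estimated correlation was -0.0032 for lipogenesis and -0.063 for cholangiocyte, under the preset 0.01. For these 2 lists that argues against correlated members as the cause of the lost call. For the remaining called lists it was above the preset, from 0.115 for interferon response to 0.686 for cholesterol synthesis. Their p-values at the preset may therefore be too small. Whether the 2 forms of camera differ in more than the correlation was not examined, and the cause of the losses was otherwise not tested.

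Leaving out 1 library gave adjusted p of 4.85e-06 to 0.353 for cholesterol synthesis, 0.000717 to 0.0951 for NRF2 genes, 8.55e-05 to 0.0599 for ribosomal proteins, 0.00346 to 0.177 for complement, 0.00102 to 0.589 for macrophage and 0.000207 to 0.271 for immediate early genes. The other 7 called lists stayed under 0.05 in those 6 fits, with the highest value 0.0283 for xenobiotic targets. Of the 74 called genes of the naming rule, 27 lost the call without at least 1 library and 16 under at least 1 other alternative, and none changed direction. Arntl, named after its value was seen and not called, turned from -0.13 to 0.18 with the replicate block. Leaving out 1 library gave it -0.51 (without atractylodin 2) to 0.31 (without atractylodin 1), with 0.07 without vehicle 2 and 0.06 without vehicle 3, and the cause was not tested. Genes of a few CPM are limited by the depth of vehicle 1.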

Other observations

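The tests in this part were chosen only after the results they weigh had been seen, except the fit without vehicle 1, which had been fixed earlier and was only afterwards used to weigh depth. Major urinary protein genes, which encode pheromone carriers made by male liver, were the most enriched family among the rises. Grouping symbols by their letter root gave 16 of 20 tested Mup genes higher where 0.784 would be expected (one-sided Fisher's exact test, adjusted p = 3.84e-17 over 376 tests). Their summed level was 37605 ± 6059 CPM with vehicle and 58846 ± 5879 CPM with atractylodin (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 allows). The Mup copies are near-identical, so their calls are not independent. Glucuronosyltransferase genes followed, with 6 of 14 Ugt genes higher (0.549 expected, adjusted p = 0.00152), and the 7 Ugt2b genes summed to 1385 ± 115 and 2313 ± 257 CPM. Those 6 are all Ugt2b genes from 1 region of chromosome 5. Their calls are not independent either, although Fisher's test treats them so. Cyp genes went both ways: of 66, 11 were higher (2.59 expected, adjusted p = 0.00571) and 7 lower (2.20 expected, adjusted p = 0.232), with a median log2 fold change of 0.07. The same limit holds for Cyp, whose rises include close paralogs (Cyp2a4 and Cyp2a5, the Cyp4a genes) and the overlapping Cyp2c29 and Cyp2c53-ps.

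The tests below were revised along the way. Before any of their values were printed, the fasting list was changed, a glucocorticoid list was added because the rises of Zbtb16 and Per1 had been seen, and Arntl took the place of a clock gene that was not tested. After a first set of values was printed, the tests on the depth of vehicle 1 were replaced, because the earlier ones used genes picked with that library, and the macrophage test was made stricter by also asking for no overlap, without which its difference would have counted against that explanation.

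The number of called genes was weighed against the low depth of vehicle 1 and against chance. Without vehicle 1, 494 genes were called, 474 of them among the 906. Those 474 calls therefore did not need that library. Leaving out vehicle 3, a deeper library, gave 467 calls and kept 423. Losses can thus come from having fewer samples, so this fit cannot weigh depth for the other calls. Of the 10 splits of the 6 libraries 1, the real one, gave as many as 906 genes, and the highest other split gave 1. With 10 splits the share cannot go under 0.1. An effect of atractylodin itself stays open and was not tested apart from the groups.

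The fall of the interferon list was weighed against depth and cell content. Without vehicle 1 the mean log2 CPM of the list still differed by -0.706 ± 0.15 (SE), which argues against depth as its whole cause. Fewer macrophages could account for part of it: the interferon change exceeded the macrophage change by -0.412 ± 0.183 (SE, exact permutation p = 0.2), but vehicle 2 overlapped the atractylodin group, so these cannot be told apart. The most abundant macrophage marker, Cd5l, stood at 124 ± 29.3 and 102.1 ± 25.6 CPM (SD). A response to atractylodin stays open.

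The fall of the lipogenesis list may reflect the state of the animals at sampling, since the labels give neither feeding nor time of day. Fasting-induced genes whose values had not been seen were higher by 0.418 ± 0.103 (SE, exact permutation p = 0.1) in mean log2 CPM. Of these only Klf15 and Sik1 passed in edgeR, and Insig2, Sesn1 and Aqp9 had lower estimates. Those seen before, outside the lipid lists, differed by 0.991 ± 0.204 (SE, exact permutation p = 0.1). In the whole fasting list 7 of 26 genes rose, Pck1 and Lpin1 of the seen values among them, against 490 of all 12505 tested rows. Glucocorticoid-induced genes whose values had not been seen were higher by 0.503 ± 0.124 (SE, exact permutation p = 0.1). Of these Fkbp5, Klf9 and Sult1a1 passed in edgeR, and Tsc22d3, Sgk1 and Errfi1 did not. Those seen before differed by 0.713 ± 0.449 (SE, exact permutation p = 0.3), with a lower estimate for Lcn2 (log2 fold change -1.51). In that whole list 5 of 14 rose, but these include Zbtb16 and Per1, whose rises had prompted the list. Both explanations therefore stay open. Late-phase minus early-phase clock genes, whose values had all been seen, differed by 0.8 ± 0.264 (SE). Arntl differed by 0.55 ± 1.27 (SE), a sign set by vehicle 1 (log2 CPM of -2.26, against 1.07 and 1.05 in the other vehicle libraries). Atractylodin 1 was also low (-0.72), and no library exceeded 1.26. At such levels Arntl lay near the floor of vehicle 1 and could not decide the question. By edgeR Arntl differed by -0.13, and by -0.36 without vehicle 1, so another clock time cannot be told apart from the groups. An effect of atractylodin on these genes stays open beside them.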
